A study of Mus musculus with 9 samples.

How the data were processed

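Whole lungs of C57BL/6 mice were collected 24 hours after intratracheal inoculation with normal saline (control), conidia of Aspergillus fumigatus or hyphal fragments of the same fungus. There were 3 libraries per group and 9 in all. Per the labels' protocols, lungs were frozen on dry ice, RNA was taken up in Trizol, poly(A) RNA was purified and libraries were sequenced on a BGISEQ instrument. The labels do not say whether the 3 libraries of a group came from separate animals. If they did not, the p-values measure only the spread between these samples, which may be technical.

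The deposited values were FPKM (fragments mapped to a gene, scaled by transcript length and by the mapped fragments of the library), per the file headers, with 2 decimals and 1 file per library. HISAT, Bowtie2 and the genome build mm9 are named in the submitters' processing notes without roles or versions. The tool that computed the FPKM values is not given in the sources used here. No scaling between libraries beyond FPKM is recorded. The files listed 18984 genes by Entrez ID and symbol, of which 18763 were coding genes, 125 pseudogenes and 85 lncRNA genes. Gene names were used as the files give them. The reference annotation at hand belongs to a build other than mm9, so no coordinates are given.

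The files hold no counts, so total counts per library are unknown. The spacing of the smallest values and the transcript lengths gave an approximate depth of 20300000 to 22400000 fragments per library, on the assumption of a fragment length of 150 bases. Values near 0 are the least precise at this depth, and confidence intervals for single values were not computed.

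Computations were done in R 4.3.3 with limma 3.58.1, and jsonlite 2.0.0 was used to match each sample to its data. The design had been written for either counts or FPKM before the data were examined, as were the gene lists, the rule for naming genes and most alternatives. The branch for FPKM was used. Values were transformed to log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested (13761 genes). One limma-trend model with robust empirical Bayes moderation held all 9 libraries, with a term per group and no covariate. The 3 comparisons were conidia against control, hyphae against control and hyphae against conidia. Tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. Because 1 was added before the logarithm, fold changes of genes with low values are understated. A rank-based exact test of 3 against 3 libraries cannot give a two-sided p below 0.1, so single-gene p-values rest on the model shared across genes.

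On the log2 scale the median of all genes was shifted by more than 0.1 in both comparisons with hyphae, and by −0.07 between conidia and control. Every comparison was therefore repeated after rescaling each library by a median-of-ratios factor, and rescaled values are given beside most of the deposited ones for hyphae and where the call of a named gene for conidia was lost. Rescaling places the median gene near 0 by construction.

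A total of 46 lists were fixed, 25 for pathways and 21 for cell types or sample checks. They held 601 genes, of which 593 were in the files and 540 were tested. The pathway lists were fungal recognition, neutrophil chemoattractants and growth factors, monocyte and lymphocyte chemokines, proinflammatory cytokines, the IL-17 axis, the type 2 response, the type I interferon response, the interferon-gamma response, NF-kB feedback, the inflammasome, NADPH oxidase, acute phase and antimicrobial proteins, complement, nutritional immunity and metals, eicosanoid synthesis, matrix remodelling, glycolysis and hypoxia, oxidative stress (Nrf2), the aryl hydrocarbon receptor, lipid and sterol synthesis, MHC class II, the cell cycle, the circadian clock, the glucocorticoid response and immediate early genes. The marker lists were for neutrophils, monocytes and recruited macrophages, alveolar macrophages, dendritic cells, T cells, B cells, NK cells, eosinophils with basophils and mast cells, alveolar type 1 cells, alveolar type 2 cells, club and goblet cells, ciliated cells, endothelial cells, fibroblasts, smooth muscle cells and pericytes, erythroid cells, platelets, cardiac muscle, adipose tissue, squamous or tracheal epithelium, and Y-linked and X-linked genes as a sex check. Some genes stood on more than 1 list. Lists were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the 46 lists of a comparison. Camera compares a list with all other genes. It was repeated with a correlation estimated per list. In that setting camera also takes its degrees of freedom from the libraries and not from the number of genes. Its p-values therefore rise for this reason as well. The fry test, added after the data were seen, asks whether the genes of a list move on balance one way, and compares them with no other genes. Counts of list members were made over all genes tested and again with adjustment over the list alone.

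Genes were named by a rule. Per comparison it took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM, leaving out predicted genes and immunoglobulin or T cell receptor segments. It also took up to 4 called members of each list with the largest change, or the 2 most abundant where no member was called, and 11 genes chosen in advance. The overlap of calls between both fungal forms was set beside a simulation (100 draws). It drew all 9 libraries without any change, with independent noise per gene and 3 simulated controls shared by both comparisons.

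The procedure was tested on simulated data with 13761 genes and 50 genes changed at each size. Noise was independent per gene and each library of a group had the same change. The shares recovered may therefore not hold for the real libraries. For conidia against control, 22% of genes with a log2 change of 0.5, 84% of those with 1, 98% of those with 2 and 100% of those with 4 were recovered, with 9 false calls. For hyphae against control, the shares were 22%, 78%, 96% and 98%, with 5 false calls.

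The alternatives tried were other pseudocounts (0.1 and 0.01), no filter, median-of-ratios rescaling, quantile normalization, a fit of the 6 libraries of each comparison alone, the replicate number as a block, removal of hemoglobin genes, and leaving out each library in turn. Library weights, removal of Scgb1a1 with the hemoglobin genes, and corrections for transcript length and GC content (loess, span 0.5) were added after the data were seen. After each removal of genes the summed FPKM of all libraries was also made equal. A minimum fold of 2 was set in the design as an additional count. Mitochondrially encoded genes were not in the files used. Alternatives meant for counts were not run, because the values are FPKM.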

Results

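Poly(A) RNA of whole lung was measured in 9 libraries, 3 from mice given saline, 3 from mice given Aspergillus fumigatus conidia (the resting spores that are inhaled) and 3 from mice given hyphal fragments (the filamentous, tissue-invading form). All lungs were taken 24 hours after inoculation. Summed FPKM per library ranged from 492540 to 561250, and 12451 to 13730 genes reached 1 FPKM. The approximate depth ranged from 20300000 to 22400000 fragments and overlapped between groups. Scgb1a1, the main secreted protein of club cells, made up 11.4 to 19.7% of summed FPKM in control libraries, 8.11 to 11.5% after conidia and 5.40 to 6.74% after hyphae. The median gene stood at 5.88 to 6.33 FPKM in control libraries, 5.21 to 6.05 after conidia and 3.60 to 4.05 after hyphae. On the log2 scale the median gene was shifted by −0.07 between conidia and control, by −0.37 between hyphae and control and by −0.29 between hyphae and conidia. Values rescaled by median-of-ratios factors, which remove this shift, are given beside the deposited ones for the hyphae libraries.

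**Figure D1:**
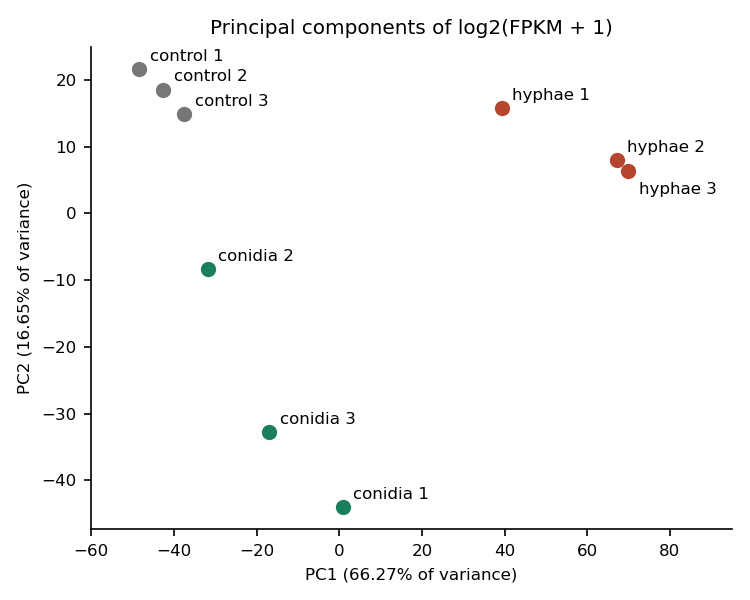
Principal components of log2(FPKM + 1) over the 13761 tested genes, with 1 point per library and colours for the 3 groups; the axes are component scores in log2 units. The first component holds 66.3% of the variance and runs from −48.4 to −37.5 in control, from −31.8 to 0.809 after conidia and from 39.3 to 69.9 after hyphae.

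Conidia were compared with saline to ask which lung transcripts had changed 1 day after spores were given. The largest rise was that of Saa3 (Entrez 20210), an acute phase apolipoprotein made in inflamed tissue, which went from 15 ± 10.7 to 1445 ± 1147 FPKM (mean ± SD, n = 3 per group), a log2 change of 6.52 (SE 0.75, adjusted p = 0.0244). Lcn2 (Entrez 16819), which withholds iron from microbes by binding their siderophores, rose from 173 ± 46.2 to 5480 ± 4138 FPKM, a log2 change of 4.57 (SE 0.74, adjusted p = 0.0441). Timp1 (Entrez 21857), an inhibitor of matrix metalloproteinases, rose from 14.5 ± 4.72 to 167 ± 99.8 FPKM, a log2 change of 3.33 (SE 0.37, adjusted p = 0.0244). Ccl3, a macrophage-derived chemokine, rose by 5.80 on the log2 scale, Acod1, the enzyme that makes itaconate, by 4.99, S100a9, a calcium-binding protein abundant in neutrophils, by 4.55, and Il1rn, the interleukin 1 receptor antagonist, by 4.14. In each of these genes all 3 conidia libraries lay above all 3 controls, as the naming rule required of all but Timp1, which was named from a list.

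In total 95 of 13761 genes differed between conidia and control, 82 higher and 13 lower, and 73 of them by a fold of at least 2 (68 higher, 5 lower). After rescaling 47 genes differed (41 higher, 6 lower), of which 45 were among the 95, and by a fold of at least 2 there were 37 (36 higher, 1 lower). Saa3, Saa1, Clec4n, Cxcl5, Zbp1, Timp1, Spp1 and Angptl4 kept their calls after rescaling, whereas the adjusted p of Lcn2 rose to 0.059, that of S100a9 to 0.0636, that of Acod1 to 0.0646 and that of Ccl3 to 0.0671. The number of calls depended on single libraries. It was 0 in limma without control replicate 1, 2 or 3 or without conidia replicate 3, where 2005, 2001, 2631 and 1878 genes had an unadjusted p under 0.05. It was 1 without conidia replicate 1 (Timp1), 7 without hyphae replicate 2, 233 without hyphae replicate 1 and 1535 without conidia replicate 2 (657 higher, 878 lower), among which were all of the 95. None of the 34 named genes with a call for conidia, in this paragraph and the others on conidia, kept it without each library in turn.

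Genes for sensing fungi and for calling in leukocytes were higher after conidia. Of 19 measured genes for fungal recognition 3 rose (1 rescaled), and 11 did when adjusted over the list alone (camera adjusted p = 3.2e-10; adjusted p = 0.22 with an estimated correlation). They were the C-type lectin receptors Clec4d (log2 change 3.84, SE 0.65), Clec4e (3.82, SE 0.60) and Clec4n (1.84, SE 0.25), the last known as dectin-2 and the only one called after rescaling (Clec4d 0.0642, Clec4e 0.059). Clec7a, the beta-glucan receptor dectin-1, stood at 12.1 ± 2.28 FPKM in control and 24.3 ± 7.87 after conidia, a log2 difference of 0.91 that did not pass (adjusted p = 0.26). Cxcl5 rose by 3.40 among 9 neutrophil chemoattractants and growth factors, of which 6 rose when adjusted over the list alone (camera adjusted p = 8.69e-05). Cxcl1 and Cxcl2, both ligands of the neutrophil receptor Cxcr2, had log2 differences of 4.01 (adjusted p = 0.0595) and 5.74 (adjusted p = 0.0583). Ccl3 and Ccl20 rose among 20 monocyte and lymphocyte chemokines (10 adjusted over the list alone, camera adjusted p = 5.54e-07), and Cxcl10 had a log2 difference of 2.67 (adjusted p = 0.0582). Tnf rose by 3.85 and Il1rn by 4.14 among 13 proinflammatory cytokines (10 adjusted over the list alone, camera adjusted p = 5.83e-08), while Il6 (2.42, adjusted p = 0.116) and Il1b (3.63, adjusted p = 0.0865) did not pass. For each of the last 3 lists the adjusted p was 0.22 with an estimated correlation. After rescaling no chemokine or cytokine of the last 2 was called (Ccl3 0.0671, Ccl20 0.0624, Tnf 0.0592, Il1rn 0.0534). Without control replicate 1, 2 or 3 or conidia replicate 3 no gene was called, so these gene calls were lost there.

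Marker genes of neutrophils were higher as a group. Of 20 measured 3 rose (S100a9, Mmp8 by 3.17 and Csf3r by 2.29, the receptor of granulocyte colony-stimulating factor), and 16 rose when adjusted over the list alone, with a median log2 difference of 2.49 (camera adjusted p = 1.2e-15; adjusted p = 0.22 with an estimated correlation). The per-library medians of these markers, relative to the control mean, were 2.96, 1.64 and 2.52 for conidia replicates 1, 2 and 3 and lay above 0 alongside the gene groups above. S100a8 (4.44, adjusted p = 0.0525) and Ly6g (2.36, adjusted p = 0.0933) did not pass. After rescaling none of these markers was called (S100a9 0.0636, Mmp8 0.0624, Csf3r 0.0624). Of 15 markers of monocytes and recruited macrophages only F10 rose, by 2.01 (adjusted p = 0.0686 rescaled), while 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000834; adjusted p = 0.22 with an estimated correlation). None of these gene calls remained without control replicate 1, 2 or 3 or conidia replicate 3, where no gene was called.

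Effector genes followed the same direction. Of 17 acute phase and antimicrobial genes 6 rose (4 rescaled), among them Saa1 by 4.57 and Orm1 by 4.55 (adjusted p = 0.059 rescaled), and 11 rose when adjusted over the list alone (camera adjusted p = 2.4e-11). Among 14 matrix remodelling genes 4 rose, Timp1, Mmp8, Spp1 (1.79, SE 0.26) and Mmp3 (1.46, SE 0.23), of which Timp1 and Spp1 were called after rescaling (Mmp8 and Mmp3 0.0624), and 9 did when adjusted over the list alone (camera adjusted p = 3.98e-10). Slc40a1, the iron exporter ferroportin, rose by 0.89 among 13 genes of nutritional immunity and metals, 11 of which rose when adjusted over the list alone (camera adjusted p = 2.44e-10). Angptl4, Fkbp5 and Lcn2 rose among 12 glucocorticoid-responsive genes (10 adjusted over the list alone, camera adjusted p = 2.4e-11), Lcn2 and Ccl20 among 12 genes of the IL-17 axis (5 adjusted over the list alone, camera adjusted p = 2.92e-06), and Gsr, glutathione reductase, among 12 Nrf2 targets (4 adjusted over the list alone, camera adjusted p = 1.71e-06). With an estimated correlation the adjusted p was 0.22 for each of these 6 lists. Cyba, the membrane subunit p22phox, rose by 0.67 among 6 genes of the NADPH oxidase (3 adjusted over the list alone, camera adjusted p = 0.000486; adjusted p = 0.34 with an estimated correlation). After rescaling the calls of Slc40a1 (0.0581), Fkbp5 (0.0624), Lcn2 (0.059), Ccl20 (0.0624), Gsr (0.0624) and Cyba (0.0738) were lost. These gene calls, too, were lost where control replicate 1, 2 or 3 or conidia replicate 3 was left out and 0 genes were called.

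Several lists were called as higher with few or no called members. Zbp1, a sensor of Z-form nucleic acids, rose by 1.35 among 19 type I interferon response genes, of which 8 rose when adjusted over the list alone (median 0.62, camera adjusted p = 1.59e-08; adjusted p = 0.27 with an estimated correlation). No member passed among 16 genes of NF-kB feedback (median 1.06, 10 adjusted over the list alone, camera adjusted p = 7.28e-09; adjusted p = 0.28 with an estimated correlation) or among 15 complement genes (median 0.15, 5 adjusted over the list alone, camera adjusted p = 0.00258; adjusted p = 0.34 with an estimated correlation). None passed among 16 interferon-gamma response genes (median 0.40, camera adjusted p = 0.00667), 20 genes of glycolysis and hypoxia (0.29, 0.00227) and 16 endothelial markers (0.20, 0.0139, with 2 that rose when adjusted over the list alone), for which the adjusted p was 0.60, 0.40 and 0.60 with an estimated correlation. These last calls were lost without conidia replicate 2 for interferon-gamma (adjusted p = 0.0726), without control replicate 2 for glycolysis (0.0583) and without control replicate 1 for endothelial markers (0.538), and that of Zbp1 without control replicate 1, 2 or 3 or conidia replicate 3, where 0 genes were called.

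Genes of the airway epithelium and of lymphocytes lay lower. Cbr2, a carbonyl reductase of club cells, fell from 7162 ± 1199 to 2732 ± 777 FPKM (log2 change −1.41, SE 0.25, adjusted p = 0.047), as the only called member of 12 club and goblet cell markers (5 adjusted over the list alone, camera adjusted p = 0.031; adjusted p = 0.60 with an estimated correlation). The other named falls were Rec8 (−1.33), a meiotic cohesin, Thbs3 (−1.33), a thrombospondin, Plekhd1 (−1.02), Slc23a2 (−0.92), a vitamin C transporter, Pdgfa (−0.80), Tmprss2 (−0.79), an epithelial serine protease, and Plagl1 (−0.78), each with an adjusted p of 0.0441 to 0.047. After rescaling the calls of Rec8 (0.059), Thbs3 (0.059) and Pdgfa (0.0592) were lost. No member passed on the other 8 lists called as lower. Their medians were −0.66 for 15 ciliated cell markers (camera adjusted p = 0.00286), −0.53 for 10 smooth muscle and pericyte markers (0.0146), −1.07 for 11 B cell markers (0.00344), −0.43 for 11 T cell markers (0.0236), −0.75 for 9 NK cell markers (0.0348), −0.74 for 10 MHC class II genes (0.00194), −0.48 for 17 cell cycle genes (6.51e-06) and −0.28 for 14 genes of lipid and sterol synthesis (0.00656). With an estimated correlation the adjusted p was 0.60, 0.40, 0.57, 0.63, 0.63, 0.57, 0.40 and 0.22, in the same order. Adjusted over the list alone, 8 cell cycle genes, 2 lipid genes, 1 ciliated and 1 smooth muscle marker fell. Libraries of a group differed on these tissue lists. Per-library medians, in the order of replicates 1, 2 and 3, were 0.37, −0.01 and −0.35 in control and −1.10, −0.30 and −0.67 after conidia for ciliated cells, and 0.37, −0.17 and −0.55 against −1.19, −0.44 and −0.29 for club and goblet cells. Markers of adipose tissue, which had no call, stood at 2.33, −1.95 and −0.26 against −2.58, −1.02 and −0.28, and those of cardiac muscle at 1.04, −0.65 and −0.48 against −1.47, −1.02 and −0.66.

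The lymphoid lists did not move alike in the 3 conidia libraries. Per-library medians of B cell markers were −1.49, −0.05 and −1.50 for conidia replicates 1, 2 and 3, and those of MHC class II genes were −1.09, −0.02 and −1.15. The T cell call was lost without conidia replicate 3 (adjusted p = 0.192), conidia replicate 1 (0.0568) or control replicate 2 (0.0826). The NK cell call was lost without conidia replicate 1 (0.128), conidia replicate 3 (0.177), control replicate 1 (0.0922), control replicate 2 (0.0955) or hyphae replicate 1 (0.0612). The club cell list lost its call without control replicate 1 (0.365) or conidia replicate 2 (0.0552), and the lipid list without conidia replicate 2 (0.072). Sftpc, the surfactant protein of alveolar type 2 cells, stood at 21010 ± 4352 FPKM in control and 14190 ± 5692 after conidia and did not pass (log2 difference −0.62, adjusted p = 0.225). Il17a was below the filter, at 0.05, 0 and 0 FPKM in control replicates 1 to 3 and 1.56, 0.59 and 0.14 in conidia replicates 1 to 3.

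For conidia 28 of the 46 lists were called, 19 higher and 9 lower, and all 28 kept their call after rescaling. None was called with an estimated correlation, where the smallest adjusted p was 0.22. The 18 lists without a call had camera adjusted p of 0.0533 to 0.859, from eicosanoid synthesis to squamous or tracheal epithelium. Median, mean and test differed in sign for 7 lists, none of them called.

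Hyphae were compared with saline to ask the same of the filamentous form. The largest rises were in neutrophil chemoattractants. Cxcl2 (Entrez 20310) rose from 1.33 ± 0.99 to 817 ± 762 FPKM (n = 3 per group), a log2 change of 7.97 (SE 1.12, adjusted p = 0.000378; 8.30 rescaled), and Cxcl1 (Entrez 14825) rose from 1.03 ± 0.722 to 232 ± 168 FPKM, a log2 change of 6.65 (SE 0.80, adjusted p = 0.000185; 6.97 rescaled). Mt2 (Entrez 17750), a metallothionein that binds zinc and copper, rose from 56.0 ± 25.1 to 2427 ± 1345 FPKM, a log2 change of 5.38 (SE 0.67, adjusted p = 0.000218; 5.79 rescaled). The deepest fall was that of Sox18 (Entrez 20672), an endothelial transcription factor, from 78.3 ± 21.4 to 2.03 ± 0.311 FPKM, a log2 change of −4.68 (SE 0.22, adjusted p = 1.89e-05; −4.34 rescaled). In each of these genes the 3 hyphae libraries lay on the same side of all 3 controls, as the naming rule required.

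The other large rises were in Ngp (6.17, 6.51 rescaled), a granule protein of immature neutrophils, Il1r2 (5.53 and 5.85), a decoy receptor for interleukin 1, Adm (5.39 and 5.76), the vasodilator peptide adrenomedullin, Csf3 (5.14 and 5.39), granulocyte colony-stimulating factor, and Egr4 (4.87 and 5.10), an inducible transcription factor. The other large falls were in Gja5 (−3.37 and −3.13), the connexin of arterial endothelium, Rnf186 (−3.18 and −2.87), Tnfsf10 (−3.10 and −2.76), the death ligand TRAIL, Fam216b (−2.93 and −2.65), Prr18 (−2.92 and −2.69), Mgat3 (−2.89 and −2.57), a glycosyltransferase, and Ldlrad1 (−2.86 and −2.52). Hyphae changed 8931 of 13761 genes relative to control. As deposited 2045 were higher and 6886 lower. After rescaling 8185 genes differed, 4058 higher and 4127 lower, and 6172 of the 8931 kept call and direction. By a fold of at least 2, 2983 genes differed as deposited (660 higher, 2323 lower) and 2336 after rescaling (1234 higher, 1102 lower).

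**Figure D2:**
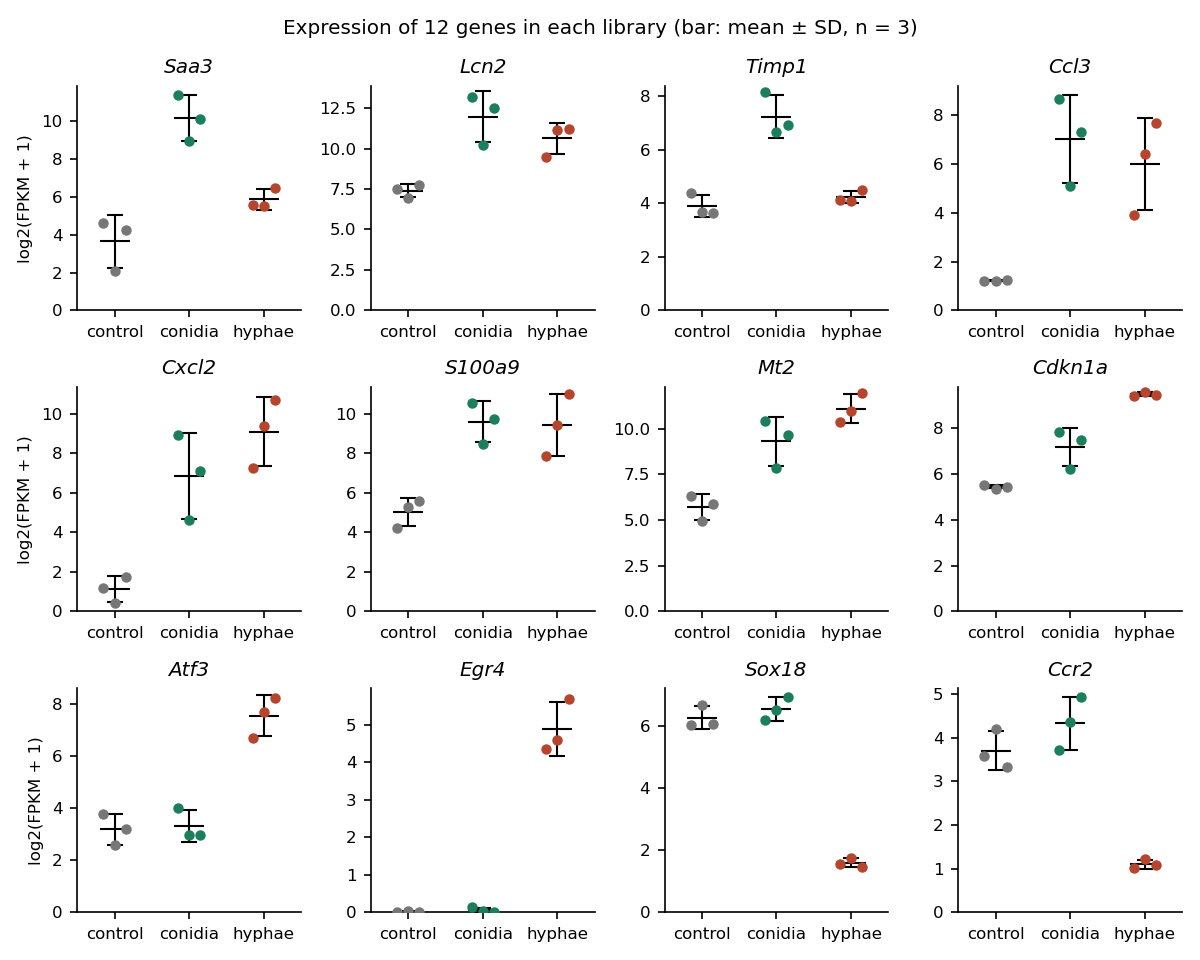
Expression of 12 genes as log2(FPKM + 1), with 1 point per library and a bar at the mean ± SD of the 3 libraries of each group. Saa3 has its highest mean after conidia (1445 FPKM), Cxcl2, Mt2, Cdkn1a, Atf3 and Egr4 have theirs after hyphae (817, 2427, 723, 206 and 31.1 FPKM), and Sox18 and Ccr2 have their lowest after hyphae (2.03 and 1.16 FPKM).

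Stress and feedback genes rose together after hyphae. Of 12 glucocorticoid-responsive genes 11 rose, among them Cdkn1a, the cell cycle inhibitor p21, from 42.6 ± 2.04 to 723 ± 48.8 FPKM (log2 change 4.05, SE 0.34, adjusted p = 4.37e-05; 4.47 rescaled), and Mt1 (3.89, 4.31 rescaled). Of 13 immediate early genes 10 rose and 1 fell as deposited, and 11 rose and none fell after rescaling, among them Atf3 (4.37, 4.76 rescaled), Fosb (3.50 and 3.86) and Egr1 (3.29 and 3.71). Of 16 genes of NF-kB feedback 13 rose and 1 fell, including Socs3 (4.30, 4.71 rescaled), Tnfaip3 (4.13 and 4.52) and Nfkbia (3.28 and 3.69), all of which restrain inflammatory signalling. Of 12 Nrf2 targets 8 rose and 1 fell (9 and 0 rescaled), among them Osgin1 (2.42, 2.82 rescaled), Txnrd1 (2.29 and 2.70), thioredoxin reductase, and Gclc (2.06 and 2.47), which starts glutathione synthesis. The camera adjusted p of these lists was 2.7e-08, 2.19e-07, 7.53e-08 and 3.56e-05, and the adjusted p was 0.62, 0.62, 0.71 and 0.62 with an estimated correlation.

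Neutrophil-directed signals also rose. Of 20 neutrophil markers 13 rose and none fell, with Retnlg at 4.78 (5.18 rescaled), S100a9 at 4.40 (4.81) and S100a8 at 4.35 (4.76). Their camera adjusted p was 7.53e-08 (adjusted p = 0.71 with an estimated correlation). Per-library medians of these markers differed within the group, at 0.69, 2.18 and 3.44 for hyphae replicates 1, 2 and 3. In the IL-17 axis 9 of 12 rose and 1 fell (9 and 0 rescaled), including Zc3h12a (3.39, 3.78 rescaled), Lcn2 (3.22 and 3.63) and Nfkbiz (2.83 and 3.23), with a camera adjusted p of 1.45e-05 (adjusted p = 0.62 with an estimated correlation). Among 13 proinflammatory cytokines 7 rose and 2 fell (7 and 0 rescaled), with Il6 at 4.26 (4.54 rescaled), Tnf at 4.03 (4.33) and Il1a at 2.96 (3.30). Among 20 monocyte and lymphocyte chemokines 9 rose and 1 fell (10 and 1 rescaled), with Ccl3 at 4.78 (5.11 rescaled), Ccl4 at 3.93 (4.26) and Cxcl10 at 3.64 (4.02). The last pair of lists had camera adjusted p of 0.000459 and 0.000314 (adjusted p = 0.71 for both with an estimated correlation). Of 9 neutrophil chemoattractants 5 rose and 1 fell (5 and 0 rescaled; camera adjusted p = 0.00184, and 0.0686 rescaled; adjusted p = 0.62 with an estimated correlation).

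Further lists were called as higher after hyphae. Of 20 genes of glycolysis and hypoxia 7 rose and 4 fell as deposited, and 12 rose and 1 fell after rescaling, including Hk2 (2.41, 2.78 rescaled), Hif1a (1.78 and 2.19) and Slc2a1 (1.04 and 1.44), with a camera adjusted p of 0.00562 (adjusted p = 0.76 with an estimated correlation). Of 8 platelet genes 6 rose (7 rescaled), including Gp1bb (0.95, 1.29 rescaled) and Itga2b (0.88 and 1.24), with a camera adjusted p of 0.000893 (adjusted p = 0.71 with an estimated correlation). Matrix remodelling genes (5 of 14 rose, as deposited and rescaled, among them Mmp8 at 3.89 and Mmp9 at 1.92, or 4.21 and 2.28 rescaled) had a camera adjusted p of 0.00243, nutritional immunity genes (4 rose and 2 fell of 13, and 6 and 1 rescaled) of 0.0189, and fungal recognition genes (7 rose and 4 fell of 19, and 9 and 3 rescaled, with Tlr2 at 2.60 and Clec4e at 2.38, or 2.98 and 2.69 rescaled) of 0.022. Of 17 acute phase and antimicrobial genes 3 rose and 2 fell (5 and 1 rescaled), with Camp, the antimicrobial cathelicidin, at 4.40 (4.71 rescaled) and Pigr, the carrier of secreted antibodies, at −1.67 (−1.28 rescaled; camera adjusted p = 0.0371). Of 16 endothelial markers 5 rose and 2 fell (8 and 1 rescaled), with Calcrl, the adrenomedullin receptor, at −2.51 (−2.10 rescaled) and Robo4 at 1.14 (1.55 rescaled; camera adjusted p = 0.022), of 13 alveolar type 1 cell markers 2 rose and 2 fell as deposited and 8 rose and 1 fell rescaled (0.0415), and of 5 erythroid genes none passed (0.0433). With an estimated correlation the adjusted p of these 7 lists was 0.76, 0.76, 0.77, 0.76, 0.78, 0.89 and 0.78. After rescaling it was 0.0514, 0.174, 0.285, 0.424, 0.0413, 0.0686 and 0.285 with the preset correlation. Fungal recognition lost its call without hyphae replicate 3 (0.063), the acute phase list without control replicate 2 (0.121) or hyphae replicate 3 (0.0836), and endothelial markers without control replicate 1 (0.151). Alveolar type 1 markers lost theirs without control replicate 1 (0.296), hyphae replicate 1 (0.102) or hyphae replicate 2 (0.0649), and erythroid genes without conidia replicate 1 (0.0514), control replicate 1 (0.203), control replicate 2 (0.0622), hyphae replicate 2 (0.0811) or hyphae replicate 3 (0.0867).

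Ciliated cell genes fell throughout the list. All 15 measured fell as deposited and 14 after rescaling, with a median of −1.73 (−1.35 rescaled). The camera adjusted p was 0.0252 (0.00201 rescaled), and the adjusted p was 0.94 with an estimated correlation. Per-library medians were −0.82, −2.11 and −2.18 for hyphae replicates 1, 2 and 3, so the fall was smaller in replicate 1. Foxj1, the transcription factor of motile cilia, fell from 86.5 ± 25.9 to 22.6 ± 16 FPKM (log2 change −2.05, SE 0.42, adjusted p = 0.00262; −1.65 rescaled), Sntn by 2.55 (2.22 rescaled) and Ccdc39 by 2.33 (1.98) on the log2 scale. Of 12 club and goblet cell markers 9 fell and 1 rose (7 and 1 rescaled), including Cyp2f2, a club cell cytochrome, at −2.03 (−1.61 rescaled), without a camera call (0.374). Of 11 B cell markers 10 fell (6 rescaled), including Spib at −2.22 (−1.94 rescaled), and the list was called after rescaling (camera adjusted p = 0.0211) and not as deposited (0.125; adjusted p = 0.94 with an estimated correlation). Falls were also counted among T cell markers (6 of 11; 5 fell and 2 rose rescaled), NK cell markers (5 of 9; 4 rescaled) and dendritic cell markers (7 of 13; 5 rescaled), including Clec9a at −1.67 (−1.33 rescaled). These lists had camera adjusted p of 0.858, 0.537 and 0.39.

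Monocyte and interferon genes split. Of 15 monocyte and recruited macrophage markers 7 fell and 1 rose (5 and 2 rescaled; camera adjusted p = 0.818), with Ccr2 (Entrez 12772), the chemokine receptor of inflammatory monocytes, falling from 12.5 ± 4.29 to 1.16 ± 0.156 FPKM (log2 change −2.60, SE 0.30, adjusted p = 0.000171; −2.30 rescaled), Cx3cr1 at −2.34 (−2.15 rescaled) and Ly6c1, which endothelium also makes, at 1.57 (1.99). Of 19 type I interferon response genes 11 fell and 3 rose (5 and 4 rescaled; camera adjusted p = 0.776), with Oasl2 at −1.76 (−1.37 rescaled) and Oasl1 at 1.45 (1.79). Of 16 interferon-gamma response genes 7 fell and 2 rose (3 and 2 rescaled), with Irgm2 at −1.91 (−1.56 rescaled) and Irf1 at 1.44 (1.85), and their median turned from −0.32 to 0.06 on rescaling (camera adjusted p = 0.735). Alveolar type 2 markers also went both ways, with 5 lower and 1 higher as deposited and 2 lower and 4 higher rescaled (camera adjusted p = 0.747), and Slc34a2, their phosphate transporter, fell by 2.19 (1.78 rescaled) on the log2 scale. Sftpc, at 22680 ± 1805 FPKM, did not differ by the test (log2 difference 0.13, adjusted p = 0.681; 0.55 rescaled). Clec7a did not pass either (−0.43, adjusted p = 0.406; −0.05 rescaled). Ly6g rose by 2.56 (2.79 rescaled), and Il1b rose by 2.87 (3.26 rescaled), a call lost without control replicate 3 (0.0538), hyphae replicate 2 (0.0575) or hyphae replicate 3 (0.0564). Il17a, below the filter, stood at 0.09, 0.27 and 4.74 FPKM in hyphae replicates 1 to 3.

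The remaining lists had no camera call. Members went both ways in the type 2 response (3 rose and 3 fell of 8, and 3 and 2 rescaled, adjusted p = 0.276), the circadian clock (3 and 4 of 14, rescaled 5 and 1, 0.18), eicosanoid synthesis (2 and 3 of 11, rescaled 3 and 1, 0.547), the inflammasome (2 and 5 of 10, rescaled 3 and 3, 0.818), the aryl hydrocarbon receptor list (1 and 2 of 5, rescaled 1 and 1, 0.818), complement (1 and 1 of 15, rescaled 3 and 1, 0.516), eosinophils with basophils and mast cells (1 and 2 of 6, rescaled 1 and 1, 0.755) and fibroblasts (1 and 3 of 13, rescaled 2 and 1, 0.818). Among them Il4ra rose by 2.65 (3.06 rescaled), Per1 by 2.91 (3.32) and Tiparp by 2.24 (2.64), and Gsdmd, the pore former of pyroptosis, fell by 1.09 (0.70 rescaled) on the log2 scale. Only falls were counted, as deposited, for the cell cycle (11 of 17, and 3 fell and 2 rose rescaled, 0.703), lipid and sterol synthesis (5 of 14, and 3 fell and 2 rose rescaled, 0.789), MHC class II (3 of 10, and 1 fell and 1 rose rescaled, 0.772), smooth muscle and pericytes (4 of 10, and 1 fell and 4 rose rescaled, 0.755), alveolar macrophages (2 of 16, and none fell and 2 rose rescaled, 0.571) and squamous or tracheal epithelium (1 of 3, and 1 fell and 1 rose rescaled, 0.86). No member passed for the NADPH oxidase (6 genes, 0.703), cardiac muscle (9, 0.818) or adipose tissue (7, 0.858). The median turned from negative to positive on rescaling for complement, eicosanoid synthesis, the NADPH oxidase, lipid and sterol synthesis, MHC class II, the circadian clock, alveolar macrophages and smooth muscle. The 4 Y-linked genes of the sex check were present in every group, and 3 fell and 1 rose as deposited, and 2 and 1 rescaled (0.825). Eif2s3y was lower as deposited (−0.36) and not after rescaling (0.04), and its call was lost without control replicate 1 (0.0819), control replicate 2 (0.133), hyphae replicate 1 (0.0853) or hyphae replicate 2 (0.118).

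For hyphae 19 lists were called, 18 higher and 1 lower. After rescaling 12 of them kept the call. None was called with an estimated correlation, where the smallest adjusted p was 0.62, and 14 kept the call without each library. Adjusted over the list alone, the counts of called lists matched those given except for the acute phase list (2 rose, 1 fell) and matrix remodelling (3 rose). Median, mean and test differed in sign for 17 lists, none of them called.

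**Figure D3:**
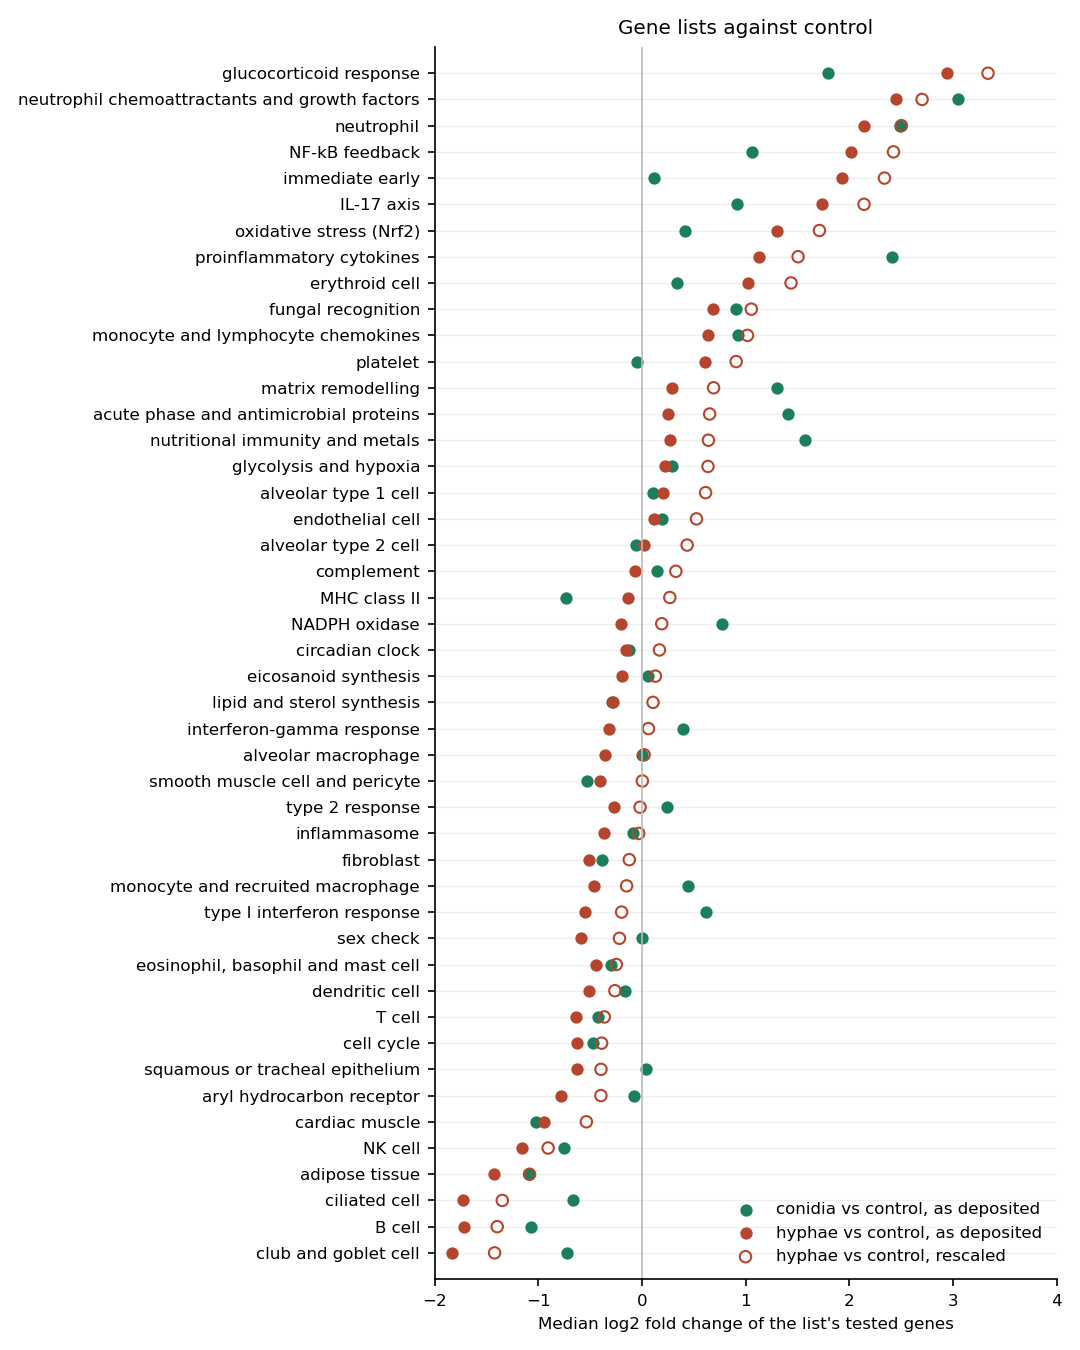
Median log2 fold change against control of each of the 46 lists, for conidia and hyphae as deposited (filled points) and for hyphae after rescaling (open points), sorted by the latter. Glucocorticoid-responsive genes have a median of 1.80 after conidia and 2.94 after hyphae (3.34 rescaled), and ciliated cell markers have −0.66 and −1.73 (−1.35 rescaled).

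The direct test of hyphae against conidia asked where the 2 forms of the fungus left different transcript levels. Egr4 and Atf3 were higher after hyphae, and Saa3 and Sox18 were lower. Egr4 (Entrez 13656) stood at 0.04 ± 0.0529 FPKM after conidia and 31.1 ± 17.0 after hyphae (n = 3 per group), a log2 difference of 4.83 (SE 0.29, adjusted p = 2.56e-05; 5.06 rescaled), and Atf3 (Entrez 11910), a stress-induced transcription factor, at 9.73 ± 4.88 and 206 ± 100 FPKM, a difference of 4.23 (SE 0.46, adjusted p = 0.000167; 4.55 rescaled). Sox18 was lower by a log2 difference of −4.97 (SE 0.22, adjusted p = 2.51e-05; −4.71 rescaled). Saa3 stood at 1445 ± 1147 FPKM after conidia and 60.6 ± 24.8 after hyphae, a difference of −4.29 (SE 0.75, adjusted p = 0.00159; −3.96 rescaled). In total 7599 of 13761 genes differed, 1752 higher and 5847 lower after hyphae. After rescaling 7013 did, 3545 higher and 3468 lower. By a fold of at least 2, 1941 genes differed as deposited (430 higher, 1511 lower) and 1537 after rescaling (821 higher, 716 lower).

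The other large differences upward were in Fosb (4.34, 4.61 rescaled), Egr1 (3.87 and 4.21), Camp (3.80 and 4.09), Adm (3.70 and 4.02), Apol8 (3.69 and 3.93) and Gdnf (3.62 and 3.93), a neurotrophic factor. Downward they were in the acute phase genes Orm2 (−4.51, −4.35 rescaled), Orm1 (−4.18 and −3.88) and Saa1 (−3.64 and −3.41), in Ccr2 (−3.23 and −3.0) and Ly6i (−3.09 and −2.79), and in the antimicrobial lectin Reg3g (−3.17 and −2.85), which lost its call without conidia replicate 2 (adjusted p = 0.0853), conidia replicate 3 (0.0678) or hyphae replicate 2 (0.0851). Of 13 immediate early genes 11 were higher and 1 lower (11 and 0 rescaled; camera adjusted p = 1.39e-07, and adjusted p = 0.95 with an estimated correlation, as for each of the next 5 lists). Of 16 NF-kB feedback genes 9 were higher and 2 lower (9 and 1 rescaled), including Rel (2.20, 2.48 rescaled) and Socs3 (2.0 and 2.33), with a camera adjusted p of 0.00139. Of 12 glucocorticoid-responsive genes 7 were higher and 1 lower, including Cdkn1a (2.31, 2.65 rescaled) and Sgk1 (1.77 and 2.10), with 0.00292. Of 12 IL-17 axis genes 6 were higher and 2 lower (6 and 1 rescaled), including Il17c (1.30, 1.5 rescaled), with 0.00982. Of 12 Nrf2 targets 5 were higher and 2 lower (5 and 0 rescaled), including Txnrd1 (1.75, 2.09 rescaled), with 0.0212, and of 8 platelet genes 6 were higher (8 rescaled), with 0.00139.

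Type I interferon genes were lower after hyphae than after conidia. Of 19 type I interferon response genes 14 were lower and none higher (12 and 2 rescaled), with a median of −1.05 (−0.78 rescaled) and a camera adjusted p of 0.0339 (0.0133 rescaled; adjusted p = 0.95 with an estimated correlation). They included Oasl2 (−2.38, −2.06 rescaled), Zbp1 (−1.90 and −1.61) and Oas2 (−1.83 and −1.57). The list lost its call without hyphae replicate 1 (0.184). Beside it, 10 of 15 monocyte and recruited macrophage markers were lower and 1 higher (8 and 1 rescaled), among them Ccr2, Ms4a4c (−2.12, −1.93 rescaled) and Cx3cr1 (−1.85 and −1.73), without a camera call (0.228). Acute phase genes were lower for 10 of 17 and higher for 1 (10 and 2 rescaled; camera adjusted p = 0.276), and complement genes were lower for 5 of 15 (3 lower and 2 higher rescaled; 0.745), among them Cfb (−2.0, −1.67 rescaled) and C3 (−1.16 and −0.83). Timp1 (−3.0, −2.67 rescaled), Il1rn (−3.08 and −2.78), Clec4n (−2.23 and −1.95) and Csf3r (−2.0 and −1.67) were lower after hyphae, although neutrophil markers had no camera call (0.276). MHC class II genes were called as higher (4 of 10 higher, 1 lower, and 6 and 1 rescaled; camera adjusted p = 0.0412; adjusted p = 0.95 with an estimated correlation), a call that was lost without conidia replicate 1 (0.107), conidia replicate 3 (0.134), hyphae replicate 2 (0.0992) or hyphae replicate 3 (0.0823).

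In this comparison 8 lists were called, 7 higher and 1 lower, and 3 of them kept the call after rescaling: immediate early genes (camera adjusted p = 0.000809), platelet genes and type I interferon genes (0.0133 each). Rescaled values were 0.163 for the IL-17 axis, 0.101 for NF-kB feedback and for glucocorticoid response, 0.124 for Nrf2 targets and 0.187 for MHC class II. None was called with an estimated correlation, where the smallest adjusted p was 0.95. The other 38 lists had no call. Median, mean and test differed in sign for 21 lists, none of them called. Tnf (0.18, adjusted p = 0.826, and 0.50 rescaled), Il1b (−0.77, adjusted p = 0.485, and −0.43 rescaled), Cxcl2 (2.23, adjusted p = 0.119, and 2.56 rescaled) and Cxcl10 (0.96, adjusted p = 0.143, and 1.30 rescaled) did not pass between the fungal forms, nor did S100a8 (−0.10, adjusted p = 0.93; 0.24 rescaled) and Ly6g (0.19, adjusted p = 0.804, and 0.48 rescaled). Clec7a was lower after hyphae than after conidia (−1.33, adjusted p = 0.0267), a call lost after rescaling (0.0965) and without conidia replicate 1 (0.0709) or conidia replicate 2 (0.088). Cxcl1 was higher (2.64, adjusted p = 0.0204, and 2.97 rescaled), a call lost without conidia replicate 2 (0.0736), conidia replicate 3 (0.0628), hyphae replicate 2 (0.0508) or hyphae replicate 3 (0.07). Il6 and Sftpc were also called as higher after hyphae. Both calls were lost without conidia replicate 3 (adjusted p = 0.135 and 0.118) and without several other libraries in turn.

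Calls were compared between the 2 fungal forms. A total of 48 genes were called in the same direction in both comparisons, 37 higher and 11 lower, and 18 were after rescaling (15 higher, 3 lower). Independent lists of the sizes called as deposited would share 18.7, a value not computed for the rescaled lists. In the simulation, where neither group was changed, 0.01 were shared. Few genes are called when none changed, so this value cannot show how much the shared controls add to the 48. Among the 37 were Ccl3, Ccl20, Lcn2, Tnf, Clec4d and Clec4e. Of the 95 genes called for conidia, 44 were not called for hyphae and 3 were called the other way, namely Armcx4 (1.42 with conidia, −1.10 with hyphae), Lilra6 (1.16 and −0.54) and Zbp1 (1.35 and −0.55). Armcx4 and Lilra6 were named after their values were seen. After rescaling the hyphae call of Armcx4 remained (−0.81, adjusted p = 0.00995), and those of Lilra6 (−0.39, 0.0908) and Zbp1 (−0.20, 0.417) did not. Across genes, the log2 changes correlated at 0.575, against 0.502 in the simulation, and their covariance was 0.215, against 0.0206. The simulated correlation was fixed in advance by the shared controls, since neither group was changed and all had equal noise. It cannot show how much of the 0.575 the controls account for. Both comparisons rest on the same 3 control libraries, which cannot be split, so part of the sharing may come from them. The overlap of 48 became 0 without control replicate 1, 2 or 3, conidia replicate 1, conidia replicate 3 or hyphae replicate 2, 151 without hyphae replicate 1 and 1056 without conidia replicate 2. In limma those settings left 0 to 7 genes called for conidia, with 1555 to 2631 at an unadjusted p under 0.05 where the overlap was 0.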

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

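The tests of scaling, of conidia replicate 2 and of monocyte markers were chosen only after the result was seen. The direct test of the difference between the 2 fungal forms singled out 8 gene lists, by camera adjusted p. These were immediate early genes (1.39e-07), NF-kB feedback (0.00139), platelet genes (0.00139), glucocorticoid response (0.00292), the IL-17 axis (0.00982) and oxidative stress (0.0212), all higher with hyphae than with conidia, MHC class II (0.0412), higher with hyphae, and the type I interferon response (0.0339), lower with hyphae. With a correlation estimated per list the adjusted p was 0.95 for each of the 8. After rescaling, calls remained for immediate early genes (0.000809), platelet genes (0.0133) and type I interferon genes (0.0133).

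The first pattern weighed was the number of genes changed by hyphae. Of the 8931 calls, 69.1% kept call and direction after rescaling, and of the calls made after rescaling 97.4% remained after a correction for transcript length and 97.6% after a correction for GC content, which argues against each of these as the whole cause. The excess of lower calls cannot be told apart from scaling, because rescaling centres the median gene and so fixes the share of lower calls, at 50.4%. Zinc finger genes of the Zfp family, a class whose transcripts are known to turn over fast, had a median rescaled change of −0.54 with hyphae, below the lowest 2.5% of 10000 random lists of like expression (−0.31). A loss of Zfp transcripts may therefore contribute, in the living lung or between death and freezing, an interval the labels do not give. Random lists lack any correlation between Zfp genes, which was not estimated, so the bound of −0.31 may be too narrow. No other class was tested for turnover, so a general loss of short-lived transcripts was not shown. Immediate early and NF-kB feedback genes rose with hyphae, with rescaled medians of 2.34 and 2.43. A broad response to hyphae stays open as well.

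The next pattern was the smaller change in conidia replicate 2, without which 1535 genes differed from control in place of 95, and which correlated with control replicate 3 at 0.9823 and with conidia replicates 1 and 3 at 0.966 and 0.98. Each control was held out in turn, and the 1535 genes of smallest p between conidia replicates 1 and 3 and the other 2 controls were taken, without use of conidia replicate 2. Of those higher after conidia, conidia replicate 2 lay above both controls in 91.5 to 94.3% and the held-out control in 34.9 to 49.8%, which argues against a mislabelled control library. Over all of these genes conidia replicate 2 moved the same way as replicates 1 and 3 in 88.9 to 93.2% (median ratio of changes 0.325 to 0.389) and the held-out control in 49.1 to 76.2% (−0.005 to 0.171), which over these genes is consistent with a weaker response. The median of conidia replicate 2 lay between 0 and those of both other conidia libraries in 20 of the 28 lists called for conidia. But it was the highest of the 3 for monocyte markers (0.545), interferon-gamma genes (0.494) and complement (0.282). It showed no fall for NK (0.333) and T cell (0.124) markers. For the lists a weaker response therefore cannot be told apart from other causes. These are another difference between animals, a smaller dose, another time course or a mixture of libraries, none of which was tested.

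The last pattern was the lower level of type I interferon genes with hyphae than with conidia. The rescaled median of −0.78 lay below the lowest 2.5% of random lists (−0.40), which by this measure goes against a general fall in the hyphae libraries. Random lists lack the correlation between interferon genes (estimated at 0.504), so this bound is too narrow to exclude it. With that correlation, and the fewer degrees of freedom of that setting, the camera adjusted p was 0.95. Without hyphae replicate 1 the call was lost (0.184). A loss of leukocytes of all types is argued against by 4 of 4 marker lists, since neutrophil (0.22), T cell (−0.02), B cell (−0.29) and NK cell (−0.33) markers differed far less. Markers of monocytes and recruited macrophages had a median of −0.78 as well, without a camera call (adjusted p = 0.101 rescaled). Fewer of these cells with hyphae may therefore account for the pattern. A difference in interferon signalling itself between the fungal forms stays open and was not tested.

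The 6 libraries of a comparison can be divided into 2 groups of 3 in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10, the real grouping, gave the most genes in limma, with 95 for conidia against control, 8931 for hyphae against control and 7599 for hyphae against conidia. The highest of the other groupings gave 0 in each, with 1409, 549 and 1757 genes at an unadjusted p under 0.05.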

How the results depend on the processing

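Library weights, removal of Scgb1a1, corrections for length and GC content, the fry test, rescaling for the overlap and, as an alternative setting for the counts of each comparison, the fold minimum named in the design were chosen only after the result was seen. The number of genes changed by conidia (95) moved with most settings. It was 43 without a filter, 47 after rescaling, and 45 and 39 after rescaling with a length or GC correction. Without hemoglobin genes it was 157, where equal totals were also set, so removal and scaling cannot be told apart. It was 57 with the replicate number as a block, 143 after quantile normalization and 5031 with library weights. These weights were 6.19 for conidia replicate 3 and 5.31 for hyphae replicate 2 and at most 2.11 for any other library. Every count with library weights therefore leaned on single libraries. Leaving out 1 library gave 0 to 1535 genes. The number stayed within 1.5 times with pseudocounts of 0.1 (116) and 0.01 (100), with the 6 libraries alone (124) and at a fold of at least 2 (73). It also did so without hemoglobin genes and Scgb1a1, again with equal totals (98). The cause was not tested.

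The number changed by hyphae relative to control (8931) stayed between 7614 (quantile normalization) and 10857 (library weights), and between 7679 and 9033 without 1 library, apart from 2983 at a fold of at least 2, a stricter threshold. Hyphae against conidia (7599) stayed between 6228 and 11022 under the same pair of settings, and between 5958 and 7922 without 1 library, apart from 1941 at a fold of at least 2. The deviations of libraries with the same replicate number correlated across genes at −0.312 to 0.425 and those of other pairs at −0.536 to 0.297. These ranges overlapped, and the highest value belonged to control replicate 2 and hyphae replicate 2. Pairing by replicate number can thus be neither shown nor excluded. With the number as a block there were 57, 8562 and 7158 genes in the 3 comparisons.

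Lists called by camera numbered 28, 19 and 8. With an estimated correlation they numbered 0, 0 and 0. The preset value of 0.01 was smaller than most estimates, but that setting also has fewer degrees of freedom. The loss of calls cannot be put down to correlation alone. For conidia the lipid and sterol list, with an estimate of only 0.0195, went from a camera adjusted p of 0.00656 to 0.22. With fry they numbered 9, 15 and 9, of which 9, 7 and 2 were also called by camera. Against control, camera called 18 lists higher and 1 lower with hyphae and fry 6 higher and 9 lower, and for hyphae against conidia camera called 7 higher and 1 lower and fry 1 higher and 8 lower. Rescaling gave 28, 13 and 3, the block 29, 20 and 8, and leaving out 1 library 26 to 31, 16 to 20 and 7 to 12. The overlap of 48 genes was 28 at a fold of at least 2, a planned setting, 18 after rescaling, 22 with the block and 0 to 1056 without 1 library.

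Among named genes the direction reversed in 3. Il5ra with hyphae against control went from −0.42 to 0.093 after quantile normalization. Eif2s3y went from −0.36 to 0.042 after rescaling, and to 0.028 and 0.089 with the length and GC corrections. Myl7 with hyphae against conidia went from 0.20, not called, to −1.47 with library weights. Those weights leaned on hyphae replicate 2. Relative to the control mean, cardiac muscle markers, Myl7 among them, had a median of −2.61 there and 1.27 in hyphae replicate 3. The cause of the 3 reversals was not tested. Differences in genes near 0 FPKM were not resolvable at this depth, and the filter removed genes with fewer than 3 libraries at 1 FPKM, such as Il17a. Alternatives for counts (another count model, another count normalization, no count filter) were not run, because the values are FPKM, and no mitochondrially encoded genes were there to remove.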

Other observations

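Some endothelial genes fell after hyphae while others rose. Relative to control, Sox18 fell by 4.68, Gja5 by 3.37 and Calcrl by 2.51 on the log2 scale, while Gpihbp1, the capillary anchor of lipoprotein lipase, rose from 133 ± 22.1 to 248 ± 6.35 FPKM (mean ± SD, n = 3, log2 change 0.92, adjusted p = 0.000333, and 1.33 rescaled). Cldn5, a tight junction protein, was higher after hyphae than after conidia by 0.64 (adjusted p = 0.00338, and 0.98 rescaled). Alveolar type 1 markers included Gprc5a at 0.88 and Pdpn at 0.87 against Rtkn2 at −1.37 (1.29, 1.28 and −0.97 rescaled). All of these kept their calls without each library. As lists, 5 of 16 endothelial markers rose and 2 fell as deposited and 8 rose and 1 fell rescaled. Of 13 alveolar type 1 markers 2 rose and 2 fell as deposited and 8 rose and 1 fell rescaled. Falls were thus few among the listed markers. Sox18 and Gja5 were not on the endothelial list, so its counts cannot show how many endothelial genes fell.

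Of 14 genes of lipid and sterol synthesis 5 fell after hyphae as deposited, and 3 fell and 2 rose rescaled, with the median turning from −0.28 to 0.11 and no camera call (adjusted p = 0.789). The falls included Hmgcs1 at −1.52 (adjusted p = 4.55e-05, and −1.12 rescaled), Insig1 at −1.32 (−0.92 rescaled) and Sqle at −1.24 (−0.86 rescaled). Among neutrophil markers, Retnlg averaged 169 ± 96.0 FPKM after conidia and 443 ± 370 after hyphae, a difference that did not pass (log2 difference 1.22, adjusted p = 0.171), and Csf3r averaged 99.8 ± 10 and 27.3 ± 16.1, which did (−2.0, adjusted p = 0.00224).

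Il17f, named after its values were seen, stood at 0.05, 0 and 0 FPKM in the controls, 1.42, 0.68 and 0.14 after conidia and 1.05, 1.45 and 4.64 after hyphae, in the order of the replicates. Markers of adipose tissue and cardiac muscle varied between libraries of the same group, with per-library medians of 2.33 and 1.04 in control replicate 1, −2.58 and −1.47 in conidia replicate 1, 1.28 and 1.27 in hyphae replicate 3 and −2.99 and −2.61 in hyphae replicate 2, relative to the control mean. The Y-linked genes of the sex check moved apart after hyphae, with Ddx3y at 0.86 (1.26 rescaled), Uty at −1.38 (−1.06) and Kdm5d at −0.80 (−0.48).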
